A study of Paralichthys olivaceus with 16 samples.

How the data were processed

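The series held 16 single-colour Agilent custom arrays of Cy3-labelled cRNA from HINAE cells in 6 groups: vehicle, empty vector and IRF10 plasmid, each with and without poly I:C, with 2 arrays per vehicle group and 3 per plasmid group. Groups were read from the sample titles. Each array had 10593 spots, of which 536 were control spots, and the others carried 9877 distinct probes of 60 bases, 20 of them in 10 spots. Probes stood for contigs on the forward strand, the same contigs on the reverse strand (4710 contigs with both), or cDNA entries, and all descriptions read Unknown.

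The authors scanned the arrays and extracted spot values with Agilent Feature Extraction 9.5, per the submitters' processing notes. Per the file headers, the deposited processed signal is an intensity in scanner units after background subtraction and detrending within the array, with no scaling between arrays. The mean spot signal and the median local background are also deposited as intensity in scanner units. The series table deposited by the authors holds log2 values. Checked against the scanner files, it equalled log2 of the processed signal minus the array's 75th percentile and minus the mean of the control arrays, with r of 0.9926 to 0.9991 and slopes of 0.9999 to 1.002 per array. Flags for well above background, saturation and outliers were taken as deposited.

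For the tests, log2 of the processed signal was averaged over the spots of a probe and scaled by subtracting the array's 75th percentile. Spots with an outlier flag (45 to 118 per array) were left out, a step that the plan written before the data were examined did not state. Keeping them was run as an alternative. Saturated spots were kept. A probe was tested if it was well above background on all arrays of at least 1 group, which left 5132 probes, 4862 of them with a value on all arrays. Between 4898 and 5467 probes per array were well above background on the slide without poly I:C and 4510 to 4858 on the other. Saturated probes numbered 482 to 521 and 327 to 362 per array. The 75th percentile of the signal was 1662 to 1874 on the first of these slides and 945 to 1058 on the other. Arrays of a group had r of 0.993 to 0.998 across probes, and arrays of different slides 0.963 to 0.987.

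A linear model with a mean for each of the 6 groups was fitted by least squares under R 4.3.3. Its variances were moderated with eBayes of limma 3.58.1 (10 residual and 1.63 prior degrees of freedom for probes with all values). From this fit 10 contrasts were taken: 2 IRF10 effects against vector, their mean and their difference, 3 poly I:C effects, 2 vector effects and their difference. For probes with missing values the fit was done on the arrays that had them. Benjamini-Hochberg adjusted p under 0.05 within a contrast made a call. Fold changes are given as at least N-fold where the dimmer group was not well above background on any array or a group was saturated. The dim group was then set on each array to the higher of its own value and the lowest signal among probes well above background. For the mean IRF10 effect the bounds of the 2 conditions were averaged. No fold is given where both groups were dim. Counts of changes of at least 2-fold, and the 2-fold probe sets, were taken from the fitted differences without these bounds.

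The plan named genes by gene name and tested fixed gene lists with camera. Neither could be done, since 0 identifiers matched the 30478 entries of the reference table, and the gene lists and the level of IRF10 gave no value. After values had been seen, the naming rule was replaced by the 2 largest rises and 2 largest falls per contrast among called contig probes. The brighter group had to be well above background on all arrays, the arrays of both groups not to overlap, and any bound to be above 1-fold. An earlier form of that rule, without the conditions on brightness, named partly different probes. The gene lists were replaced, after values had been seen, by 4 sets of probes called and changed at least 2-fold in 1 contrast, tested in 8 tests on arrays outside that contrast with camera (preset correlation 0.01), camera with an estimated correlation, and fry, each adjusted over the 8 tests. Members needed a value on all arrays.

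The correlation of vector and poly I:C effects was set against 100 simulations of unchanged groups that shared the control arrays. It was also taken with 1 control array for each side, a comparison added after the data were seen. Overlaps are given with the number expected for independent draws among the 5132 probes. Replicate numbers were checked by the correlation of same-numbered arrays in their deviations from the group means. It was over 0.1 in every pair only between vector cells with and without poly I:C (r of 0.131, 0.162 and 0.144), so the arrays were taken as paired by number in that comparison. This pairing comes from the values and not from the labels. Those arrays also had the same position on their slides, and all 8 pairs with the same position had r of 0.0192 to 0.162, so position and number cannot be told apart there. Splits of the arrays into groups of the same sizes were refitted to give the chance level of each comparison of plasmid groups. There were 10 for each pair of groups, and 100 of 200 were drawn for the mean and the difference of the IRF10 effects. For these and for the correlation of the IRF10 effects, 10 splits that moved arrays at 1 position of both slides together were added after the data were seen. Alternatives fixed before the data were examined were median scaling, quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' table, no filter on dim probes, only probes well above background on all 16 arrays, only the groups of the contrast, eBayes with trend and robust options, blocks for replicate number and slide, a 2-fold threshold, and leaving out each array. Alternatives added after the data were seen were keeping outlier spots, blocks for the side of the slide and for the array position, spike-in scaling, leaving out saturated probes, only the 8 arrays of the slide, and all settings of the set tests, including sets taken again under each scaling and filter.

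The procedure was tested on simulated data with known changes in 4862 probes. A change of 1 on the log2 scale was recovered in 79.1% to 98.5% of altered probes over the 10 contrasts, a change of 0.5 in 46.3% to 76.1%, and false calls made up 1.8% to 8.1% of the calls. A simulated set shift of -0.3 gave a camera p of 7.3e-65, and 0 of 20 random sets passed 0.05. The simulated probes varied independently, so this could not show false set calls from correlated probes. In the sets tested the estimated correlation was 0.030 to 0.394.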

Results

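HINAE cells, a line from Japanese flounder embryos, were transfected with an expression plasmid for interferon regulatory factor 10 (IRF10), with the empty plasmid, or with vehicle in place of a plasmid. IRF10 is a transcription factor of a family that controls interferon responses. The same 3 treatments were also given together with poly I:C at 1 μg/ml, a synthetic double-stranded RNA that cells sense as viral RNA. Per the labels the plasmids were used at 7.2 nM and cells were harvested at 48 h. Each RNA sample was hybridised to a single-colour Agilent array, with 2 arrays for each vehicle group and 3 for each plasmid group, 16 in all. Changes are given as log2 differences between group means of array signals scaled to the array's 75th percentile, with the standard error (SE) of the limma fit. An error after a group mean is the SD over its arrays.

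The array names its probes by contig number, with the prefix rev_ for the probe of the opposite strand, and carries no gene names. Of 9877 probes, 5132 were bright enough to test. No identifier matched the reference gene table, so no probe could be named as IRF10, interferon or any other gene, and groups of probes are described by what treatment raised or lowered them. The 8 arrays without poly I:C lay on one slide and the 8 arrays with it on another. Effects of a plasmid were therefore measured within a slide, whereas poly I:C and the slide cannot be told apart. Each treatment lay at the same array positions on both slides, with vehicle on one side of the slide, IRF10 on the other and vector on both. Plasmid and array position therefore cannot be told apart either, and agreement between the conditions also repeats the positions. Nothing in the labels says that replicates were independent transfections, so adjusted p-values could measure the spread within 1 experiment, and 2 or 3 arrays per group limit the precision.

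Without a plasmid, arrays of poly I:C-treated cells had higher signals for a group of probes, some of them near background in control cells. POC03031_1 (probe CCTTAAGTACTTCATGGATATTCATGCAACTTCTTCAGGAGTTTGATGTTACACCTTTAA) was at -6.51 ± 0.07 in controls (SD, n = 2), not well above background, and at 1.48 ± 0.07 with poly I:C (n = 2), at least 82.8-fold higher. POC01560_1 rose by 7.60 (SE 0.44, limma adjusted p = 4.4e-08). Among the falls, POC03983_1 was at least 3.07-fold lower and rev_POC05563_1 at least 2.1-fold lower, though its call was lost without poly I:C replicate 1 (adjusted p = 0.0973). In all, 1179 probes rose and 1050 fell in limma at an adjusted p of 0.05, of which 140 rose and 73 fell at least 2-fold.

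The balance of rises and falls with poly I:C depended on the scaling and on which probes were tested. With each array centred on its median, the median of all probes was -0.168, compared with -0.0078 at the scaling used throughout, and there were 814 rises and 1666 falls. Testing all probes without a filter on dim ones gave 1897 rises and 885 falls, leaving out probes saturated on any array 677 and 996, and normexp background correction with quantile normalization 733 and 826. Spike-in control probes, of which 4 could be used, moved that median to -1.55 and gave 48 rises and 4833 falls. Relative to the spike-ins, 48 of the 140 probes raised at least 2-fold still rose, 70 were above 0 and 21 fell, whereas all 73 lowered probes still fell. The 140 are therefore probes raised relative to the bulk of the array, with the slide as an open source of the difference.

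Cells with a plasmid showed a poly I:C change of similar extent. In cells with the empty vector, 1170 probes rose and 1426 fell, and in cells with the IRF10 plasmid 972 rose and 1750 fell. At least 2-fold, 166 rose and 86 fell with the vector, and 151 rose and 80 fell with IRF10. POC00398_1 was at least 38.3-fold higher with poly I:C in vector cells, and POC04897_1 rose by 6.61 (SE 0.32, limma adjusted p = 5.1e-09), although only 1 of 3 vector arrays without poly I:C measured it well above background. POC04352_1 was at least 2.19-fold lower in vector cells with poly I:C, and rev_POC03040_1 fell by 1.86 (SE 0.24). In IRF10 cells POC01062_1 was at least 279-fold higher, rev_POC05181_1 rose by 8.69 (SE 0.30) and POC05052_1 was at least 2.78-fold lower. With poly I:C rev_POC05181_1 was at 5.76 ± 0.17 (SD, n = 3), unflagged but near the level of saturated probes, so the size of its rise is uncertain. POC00899_1 fell by 1.84 (SE 0.29) there, although only 1 of 3 IRF10 arrays with poly I:C measured it well above background. Median scaling gave 958 rises and 1755 falls in vector cells. The median of all probes was then -0.131 in vector cells and -0.16 in IRF10 cells, compared with -0.0574 and -0.112 before. Spike-in scaling gave 90 rises and 4879 falls in vector cells and 88 and 4896 in IRF10 cells, with medians of -1.43 and -1.51. In vector cells, normexp background correction with quantile normalization left 745 rises and 985 falls, and testing all probes without a filter on dim ones gave 2995 and 1287. Without probes saturated on any array there were 681 rises and 1363 falls in vector cells and 511 and 1681 in IRF10 cells, where normexp correction gave 625 and 1195. Both comparisons lie across the slides.

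The empty vector by itself raised probes that poly I:C also raised. Without poly I:C, POC03031_1 was at -1.35 ± 0.61 in vector cells (SD, n = 3), at least 11.6-fold above controls, and POC01751_1 (probe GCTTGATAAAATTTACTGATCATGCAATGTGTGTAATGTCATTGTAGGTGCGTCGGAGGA) was at least 9.16-fold above them. Across all tested probes 216 rose and 256 fell in limma, but by the fitted difference 34 rose and 2 fell at least 2-fold. The 2 that fell were POC03365_1, at least 1.63-fold lower, and rev_POC05664_1, at least 1.42-fold lower. Neither was well above background on any vector array, so a 2-fold fall was not measured for them. Both lost their calls when all probes were tested without a filter, with adjusted p = 0.0955 and 0.0852. With the side of the slide as a block, POC03365_1 lost its call too (limma adjusted p = 0.0514). POC03365_1 was also lost without any 1 of the 5 arrays (adjusted p = 0.24 without control replicate 1, 0.113 without control replicate 2, and 0.0787, 0.0717 and 0.0996 without vector replicates 1, 2 and 3). rev_POC05664_1 was lost without either control replicate (0.184 and 0.135) or vector replicate 2 (0.0705). Within the 8 arrays of that slide the counts were 201 and 212. Quantile normalization gave 170 rises and 374 falls, and with normexp correction 157 and 283, while spike-in scaling gave 94 and 135, no filter 122 and 124, and the 5 arrays of the comparison alone 137 and 151. The balance turned to more rises with outlier spots kept (353 and 198) and in the authors' table (350 and 200). Fits without control replicate 1 and without control replicate 2 made 205 and 273 calls in place of 472.

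With poly I:C, the empty vector raised probes further than poly I:C did with vehicle. POC00398_1 (probe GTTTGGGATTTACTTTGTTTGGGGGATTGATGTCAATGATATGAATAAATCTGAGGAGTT) rose by 4.04 (SE 0.26, limma adjusted p = 1.2e-06), and POC01693 was at least 3.72-fold higher. In total 285 probes rose and 297 fell, and by the fitted difference 86 rose and 14 fell at least 2-fold. The 14 include both falls named next, whose bounds are under 2-fold. The largest named falls, in POC00278_1 (at least 1.26-fold lower) and rev_POC05683_1 (at least 1.15-fold lower), ended within the 8 arrays of the slide, with adjusted p = 0.131 and 0.106. POC00278_1 was also lost without either vehicle replicate (adjusted p = 0.172 and 0.123), vector replicate 2 (0.0569) or vector replicate 3 (0.0562), and rev_POC05683_1 without either vehicle replicate (0.0913 and 0.093). Those arrays alone gave 215 rises and 86 falls, the 5 arrays of the comparison 153 and 35, and no filter 202 and 97. Median scaling gave 335 rises and 78 falls and spike-in scaling 325 and 27. With the scaling used throughout, keeping outlier spots gave 355 rises and 179 falls and the values of the authors gave 352 and 184, so the balance of rises and falls was not settled. Without replicate 1 of the vehicle arrays with poly I:C 224 probes rose and 68 fell, and without replicate 2 there were 199 and 179.

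Probes raised by the vector in one condition were higher with the vector in the other condition too. Of 82 probes that the vector raised at least 2-fold with poly I:C, 29 rose and 2 fell without it, with a median of 0.38 against -0.01 for all other probes (camera adjusted p = 1.37e-15, and adjusted p = 0.0103 with an estimated correlation). Counting probes near background at their bounds, the median was 0.17. Of 33 probes that the vector raised at least 2-fold without poly I:C, 17 rose and 0 fell with it, with a median of 0.69 (camera adjusted p = 4.58e-17, and adjusted p = 0.0377 with an estimated correlation). These sets were taken from arrays of one slide and tested on the other, where each treatment lay at the same positions. Between the conditions, 63 rises were shared where 12 would be shared by independent draws, and 62 falls where 14.8 would be. Effects of array position common to both slides could add to this agreement, so independent draws do not give its chance level.

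The vector effect differed between the conditions for 387 probes in a limma test of the interaction, with 207 above 0 and 180 below. POC01693 and POC00398_1 were called above 0, but no size is given: neither was well above background in control or vector cells without poly I:C, and POC01693 was not with poly I:C alone either. rev_POC02020_1 had -3.01 (SE 0.40). rev_POC01566_1 was also called below 0, but it was saturated on all 3 arrays of vector cells with poly I:C, so its interaction is given without a size. Median scaling gave 236 above 0 and 66 below, and spike-in scaling 222 and 33, with the median of all probes at 0.134 in place of -0.0367. No filter gave 127 and 60, and the 4 groups alone 158 and 77. Without control replicate 1 there were 131 and 63.

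The vector and poly I:C effects were correlated across probes when each was compared with the same control arrays. Of 472 probes called for the vector, 416 (88.1%) moved in the same direction with poly I:C. But in 100 simulations of unchanged groups on shared controls, as many probes of lowest p, called or not, gave a mean of 89.6% (86.4% to 92.8%). Of the 34 raised at least 2-fold, 30 were among the 140 raised at least 2-fold by poly I:C. The 34 and 140 largest rises of the simulations, called or not, shared a mean of 20.6 (11 to 27), which is not a rate for calls. Calls shared in the same direction averaged 0.04 in the simulations, against 148 rises and 207 falls in the data. Groups simulated without change make almost no calls, so 0.04 is not a chance level for the sharing of 2 called lists. Across 4862 probes r was 0.635, with a simulated mean of 0.545 (0.482 to 0.602), so part of the correlation may come from the shared controls. The covariance was 0.129 against a simulated mean of 0.0225. With the vector compared with 1 control array and poly I:C with the other, which share no array, r was 0.514 and 0.555 for the 2 assignments. Of 31 probes raised at least 2-fold by the vector in each, 25 and 27 were at least 2-fold higher with poly I:C. Probes are not independent replicates, and the poly I:C side lies across slides.

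The IRF10 plasmid without poly I:C raised 1 contig far above all others. POC02895_1 (probe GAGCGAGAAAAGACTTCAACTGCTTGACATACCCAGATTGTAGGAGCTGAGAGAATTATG) was at -5.21 ± 0.47 in vector cells, not well above background, and at 3.71 ± 0.22 in IRF10 cells (SD, n = 3 each), at least 391-fold higher (limma adjusted p = 3.9e-11). The opposite-strand probe of the same contig, rev_POC02895_1, was at least 180-fold higher (adjusted p = 0.0055). Both named falls were in probes that were higher with vector than in controls. rev_POC05181_1 (probe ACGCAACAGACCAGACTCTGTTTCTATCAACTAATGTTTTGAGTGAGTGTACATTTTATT) was at 0.99 ± 0.72 in vector cells and -2.93 ± 0.36 in IRF10 cells, 15.1-fold lower, while controls were at -3.11 ± 0.39 (n = 2). POC01751_1 was at least 7.79-fold lower with IRF10 than with vector. In total 21 probes rose and 43 fell in limma, 3 and 28 of them at least 2-fold. The number of rises was unstable: it was 8 without IRF10 replicate 1, 12 and 13 without IRF10 replicates 2 and 3, 11 and 12 without vector replicates 1 and 2, 12 with no filter on dim probes, 36 with the replicate number as a block and 34 with eBayes trend and robust options.

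**Figure D1:**
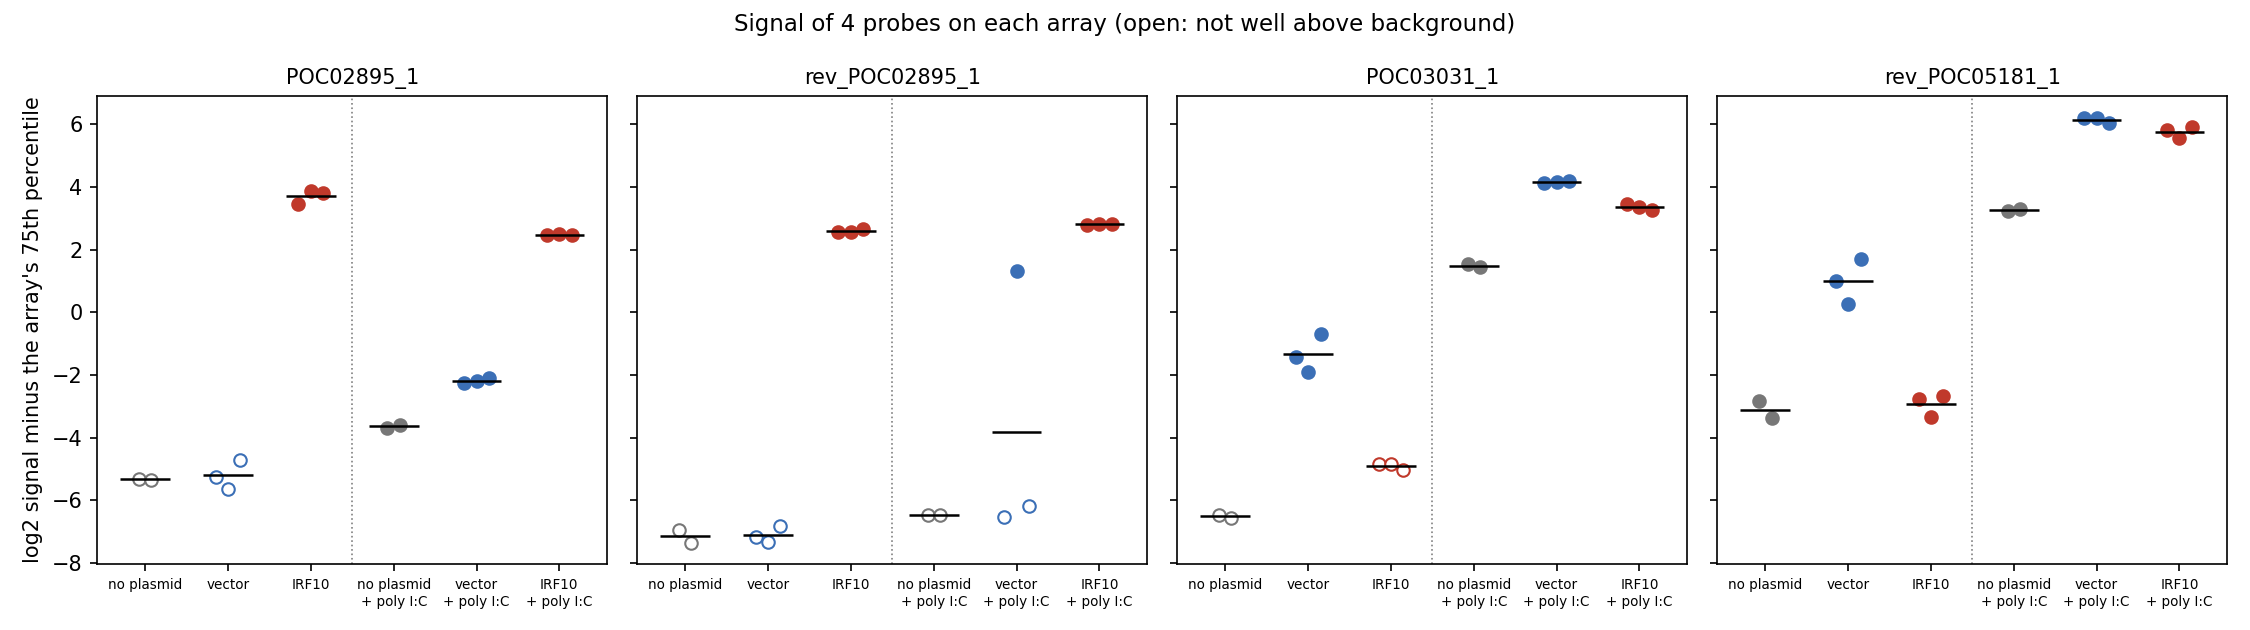
Scaled log2 signal of 4 probes on each of the 16 arrays, with horizontal bars at group means, open points for spots not well above background, and a dotted line between the slides. Both probes of contig POC02895 were high in IRF10 cells (means of 3.71 and 2.59 without poly I:C), and POC03031_1 and rev_POC05181_1 were higher in vector than in IRF10 cells without poly I:C.

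Of the 43 probes lowered by IRF10 without poly I:C, 42 were among the 1179 raised by poly I:C and 38 were among the 140 raised at least 2-fold, where independent draws would share 9.88 and 1.17. These lists came from separate arrays. Of 137 probes raised at least 2-fold by poly I:C without plasmid, 1 rose and 35 fell with IRF10 compared with vector, and the set lay lower with a median of -0.14 against 0.05 for other probes (camera adjusted p = 5.59e-31, and adjusted p = 0.00183 with an estimated correlation). With probes near background at their bounds the median was -0.02, and with the set taken again with no filter on dim probes the difference from the other probes reversed to 0.0784 (adjusted p = 0.000205). Of the 82 probes raised by the vector with poly I:C, 1 rose and 20 fell, with a median of -0.36, or -0.18 at the bounds (camera adjusted p = 4.01e-49, and adjusted p = 0.000478 with an estimated correlation). Probes lowered by poly I:C had a median of -0.06 against 0.05 for other probes, and none of the 70 passed the test singly, with 0 rises and 0 falls (camera adjusted p = 5.62e-08, and adjusted p = 0.00553 with an estimated correlation). This call was lost with the set taken again under spike-in scaling (difference of -0.0176, adjusted p = 0.622). The 8 arrays of the slide alone gave 12 rises and 19 falls, and the 6 vector and IRF10 arrays alone 9 and 18. Median scaling gave 7 rises and 61 falls, quantile normalization 12 and 51, spike-in scaling 8 and 39, and the side of the slide as a block 12 and 42.

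**Figure D2:**
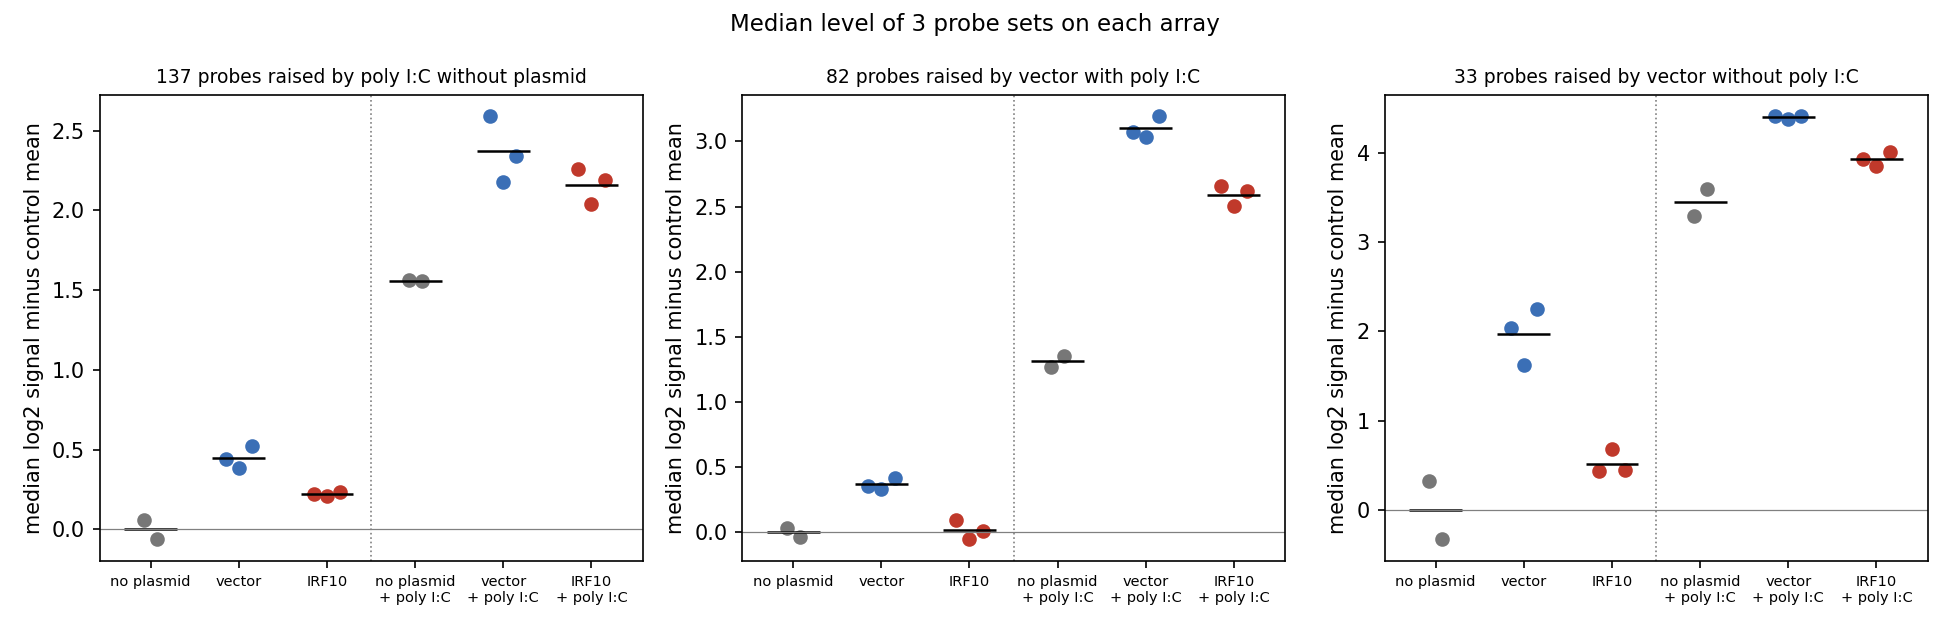
Median log2 signal of 3 probe sets on each of the 16 arrays relative to the mean of the control arrays, with horizontal bars at group means and a dotted line between the slides. In all 3 sets, each IRF10 array without poly I:C lay below each vector array without poly I:C, but the set raised by the vector without poly I:C was chosen for being high on those vector arrays, so its separation there is no test.

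With poly I:C, fewer falls with the IRF10 plasmid reached 2-fold than without it. POC02895_1 rose by 4.66 (SE 0.18, limma adjusted p = 6.9e-08) above a vector level of -2.19 ± 0.08 (SD, n = 3). rev_POC02895_1 was at 2.81 ± 0.02 in IRF10 cells, and only 1 of 3 vector arrays measured it well above background. That array, vector replicate 2, read 1.301, against -6.548 and -6.178 on replicates 1 and 3. POC02895_1 was at -2.185 on the same array, near its vector mean. The cause of this lone value was not tested, and it widens the SE of rev_POC02895_1. POC03632_1 fell by 1.13 (SE 0.15, adjusted p = 0.0031), POC00398_1 fell by 1.17 (SE 0.23, adjusted p = 0.029) and POC00659_1 was at least 1.54-fold higher (adjusted p = 0.036). In total 11 probes rose and 83 fell, with 5 and 3 at least 2-fold by the fitted difference. The 5 include POC00659_1, although its bound is 1.54-fold. With the 6 arrays of this comparison alone, POC03632_1, POC00398_1 and POC00659_1 lost their calls (adjusted p = 0.0655, 0.109 and 0.192). With the side of the slide as a block, POC00398_1 and POC00659_1 lost theirs (limma adjusted p = 0.0587 and 0.101). POC00398_1 was also lost without vector replicate 1, 2 or 3 (adjusted p = 0.0549, 0.0724 and 0.109) or IRF10 replicate 1 or 2 (0.08 and 0.107), and POC00659_1 without vector replicate 2 or 3 (0.099 and 0.0823) or IRF10 replicate 2 or 3 (0.13 and 0.109).

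Of the 83 falls with poly I:C, 31 were among the 1179 probes raised by poly I:C without plasmid and 12 among the 140 raised at least 2-fold, where independent draws would share 19.1 and 2.26. Of the 137 probes raised at least 2-fold, 1 rose and 12 fell, with a median of -0.12 against -0.01 for other probes (camera adjusted p = 0.000256). This call was lost with adjusted p = 0.182 with an estimated correlation. Of the 33 probes raised by the vector without poly I:C, 0 rose and 1 fell, with a median of -0.33 (camera adjusted p = 0.000602), a call that was also lost, with adjusted p = 0.347 with an estimated correlation. Probes lowered by poly I:C showed no shift as a set, with 0 rises and 2 falls among 70 (camera adjusted p = 0.457). The number of calls was unstable: the 8 arrays of the slide gave 4 rises and 44 falls, the 6 arrays alone 1 and 11, median scaling 13 and 166, spike-in scaling 4 and 32, and no filter on dim probes 3 and 22. Whether more probes fell with poly I:C than without it depended on the setting: 83 against 43 in the fit used throughout, but 11 against 18 with the 6 arrays of each comparison, 32 against 39 with spike-in scaling and 22 against 39 with no filter. The total of calls, 94 with all arrays, was 49 without vector replicate 1, 35 without vector replicate 3, 42 without IRF10 replicate 2 and 52 without IRF10 replicate 3, all of the poly I:C groups.

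Averaged over both conditions, both probes of contig POC02895 rose with IRF10, POC02895_1 at least 99.6-fold (limma adjusted p = 1.7e-11). For rev_POC02895_1 (adjusted p = 0.0013) no size is given, since only 1 of 3 vector arrays with poly I:C measured it, and its fitted effect ran from 7.475 to 9.437 when 1 array was left out. Vector cells without poly I:C did not measure either probe well above background. POC01751_1 was at least 3.55-fold lower (adjusted p = 0.00015) and POC01062_1 at least 3.92-fold lower (adjusted p = 0.0021), both well above background on 0 of 3 IRF10 arrays without poly I:C. In total 19 probes rose and 96 fell, with 3 and 12 at least 2-fold. Median scaling gave 9 rises and 256 falls, spike-in scaling 8 and 67, and no filter 9 and 52. The authors' table and outlier spots kept each gave 42 rises and 102 falls, and eBayes with trend and robust options 37 and 109.

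The IRF10 effects with and without poly I:C were measured on separate arrays, but each treatment lay at the same positions on both slides. They had r = 0.399 across 5082 probes, which are not independent replicates, and shared effects of position could add to r. POC02895_1, with fitted differences of 8.91 and 4.66, and its opposite-strand probe lay far above the others and could make up part of r. An r without this contig was not taken. The correlation was 0.208 with only the probes well above background on all 16 arrays, which left out both probes of this contig. With no filter on dim probes it was 0.153. Of the 64 probes called without poly I:C, 47 moved in the same direction with it, and of the 94 called with it, 72 moved in the same direction without it. The falls shared 5 probes, where independent draws would share 0.695. The 43 probes lowered without poly I:C had a median of -1.36 there and -0.32 with it, where 32 were lower and 5 passed the test. They were chosen for low values without poly I:C, so a smaller median on other arrays can follow from that choice alone. An interaction was called for 16 of the 43.

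**Figure D3:**
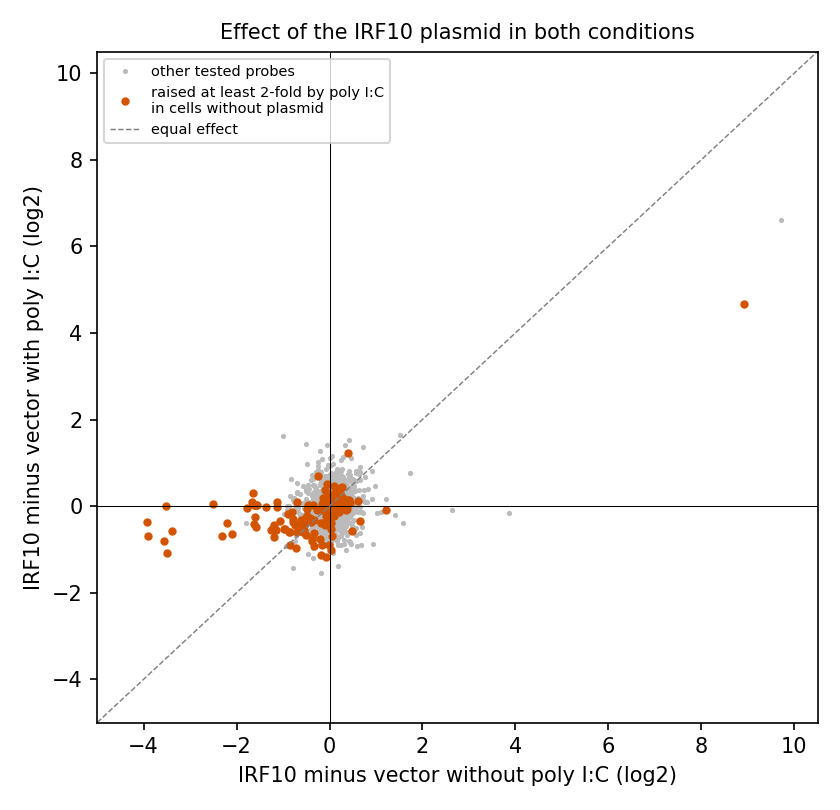
The log2 difference between IRF10 and vector arrays without poly I:C (horizontal) and with it (vertical) for each tested probe, with probes raised at least 2-fold by poly I:C in cells without plasmid in orange. Most of the larger falls were without poly I:C and in orange probes, and POC02895_1 and its opposite-strand probe lie at the far right.

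The IRF10 effect differed between the conditions for 34 probes in a limma test of the interaction, with 16 above 0 and 18 below. All 16 above 0 had fallen without poly I:C, with a median of -2.16, and had a median of -0.38 with it. All 16 were also among the probes raised at least 2-fold by poly I:C without plasmid. They included rev_POC05181_1 (adjusted p = 0.0027), which was saturated on 3 of 3 vector arrays with poly I:C. On IRF10 arrays with poly I:C it was not flagged, but its 5.76 ± 0.17 lay near the 5.78 ± 0.05 of POC01560_1, saturated on all 3. No size or bound is therefore given for its interaction. For rev_POC01566_1 (adjusted p = 0.00053) no size can be given, since it was saturated on all plasmid arrays with poly I:C. In all, 7 of the 16 had saturated spots under poly I:C, and the unsaturated ones had medians of -2.21 without poly I:C and -0.572 with it. The 18 below 0 had a median of 0.0969 without poly I:C and -0.269 with it. Of these 18, 4 were called higher and 0 lower without poly I:C, and only 5 had a smaller effect with it. Among the 18 were POC02895_1 and POC05052_1, but no size is given for them. POC02895_1 was not well above background in vector cells without poly I:C, and POC05052_1 was well above background in IRF10 cells without poly I:C and in no other group.

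The count of 34 was not stable. Median scaling gave 20 calls, normexp correction with quantile normalization 16, no filter 13, spike-in scaling 16 (10 above 0 and 6 below), outlier spots kept and the values of the authors 30 each (18 above 0 and 12 below), probes without saturation 20, and a fit with array position as a block 6. It was 13 without vector replicate 1, 14 without IRF10 replicate 1 or replicate 2, and 18 without IRF10 replicate 3. Among the arrays with poly I:C it was 21 without vector replicate 1, 14 without vector replicate 3, 18 without IRF10 replicate 2 and 15 without IRF10 replicate 3. POC05052_1 lost its call with normexp correction (adjusted p = 0.276) and with array position as a block (0.0598), as did rev_POC05181_1 with that block (0.0501).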

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

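In this part, the tests of the opposite-strand signal, of the transfected insert, of compressed signals, of probes with no saturated spot, of splits with positions kept together and of the DCP_22 control probes were chosen after the result was seen, as were the probe sets behind the medians. The count of saturated spots was planned before it was seen, but its verdict was changed from a plain bound of 50% to a binomial interval afterwards. The reading of the drawn splits was also changed after the result was seen.

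The effect of IRF10 differed between conditions for 34 probes and that of the vector for 387, both by limma tests of the interaction. Named probes with a different IRF10 effect were rev_POC05181_1 (3.54), rev_POC01566_1 (3.52), POC02895_1 (-4.25) and POC05052_1 (-4.03). Those with a different vector effect were POC01693 (4.0), POC00398_1 (3.82), rev_POC01566_1 (-3.25) and rev_POC02020_1 (-3.01). These are fitted values and, except for rev_POC02020_1, not measured sizes, since the probes were saturated or near background in 1 or more of the groups. Control probes of the DCP_22 series, outside the tested measurement, were brighter by a median of 3.84 on the slide with poly I:C.

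Other splits of the arrays were used to see whether chance groupings give results as large. For IRF10 against vector, 1 of the 10 splits, the real one, gave as many calls both without poly I:C (64, highest other 0) and with it (94, highest other 2). For poly I:C the real split was also the 1 of 10 in vector cells (2596, highest other 0) and in IRF10 cells (2722, highest other 1). In vector cells same-numbered arrays deviated together, by number or by position, and the 3 other splits that part all 3 such pairs made 0 calls. With 10 splits a share under 0.05 cannot be reached. For the mean IRF10 effect 1 of 100 drawn splits gave as many calls (115, highest other 23), for the correlation between conditions 1 of 100 (0.399, highest other 0.252) and for the interaction with poly I:C 1 of 100 (34, highest other 30). The drawn splits ignored that arrays at 1 position of both slides deviated together, so their planned reading was not used. With such arrays moved together, 1 of 10 splits gave as large a result for the mean (115, highest other 1), the correlation (0.399, highest other 0.252) and the interaction (34, highest other 0). With position also as a block it was 1 of 10 for the interaction (6, highest other 1). These splits are too few for a share under 0.05. The split that exchanges all labels under poly I:C alone turns the interaction into the mean effect and was not among those drawn. Among the drawn splits the interaction lay close to the highest other split. The correlations included both probes of contig POC02895, whose large IRF10 differences could raise the real value. They therefore do not show agreement across the other probes.

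The medians of probe sets were compared with those of other splits in the same way, with the real difference from the other probes given first. Without poly I:C, the probes raised by the vector with poly I:C had 1 split of 10 as far from 0 (-0.41, highest other 0.221), those raised by poly I:C 1 (-0.187, highest other 0.164), and those lowered by poly I:C 2 (-0.106, highest other 0.107). With poly I:C, the probes raised by the vector without it had 1 (-0.319, highest other 0.154), those raised by poly I:C 2 (-0.106, highest other 0.13), and those lowered by it 6 (0.0135, highest other 0.0851). The splits were too few for a share under 0.05.

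Contig POC02895 was high on both strands in IRF10 arrays. A bright transcript read by the opposite-strand probe as well would give pairs raised together. Of 11 contigs with a probe raised at least 16-fold by poly I:C, 9.09% (exact 95% interval 0.23 to 41.3) had an opposite-strand probe raised as much. At least 2-fold it was 4 of the 11 (36.4%, exact 95% interval 10.9 to 69.2), which left this explanation open. These counts use fitted folds without bounds. The 1 pair raised 16-fold on both strands, contig POC03031, was not well above background on either strand in controls, so the size of the rise of rev_POC03031_1 was not measured. Transcripts of the transfected insert were not excluded. That 0 other contigs were at least 16-fold higher with IRF10 in both conditions restates the observation and gives no support for them, and the identity of the contig was not known.

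The falls under IRF10 were smaller with poly I:C in the 16 probes with an interaction above 0. Saturated spots could hide a difference, and 7 of these probes had one under poly I:C (43.8%, exact 95% interval 19.8 to 70.1), which left the question open for them. The 9 with no saturated spot on any plasmid array cannot owe the smaller fall to saturation. Compressed signals on the slide with poly I:C were not seen in 4 spike-in probes (slope 1.01, SE 0.183), but 11 of the 16 probes were brighter than those spike-ins, so compression cannot be told apart from a smaller effect of IRF10. Condition and slide coincide here too, and a biological difference between conditions remains among the open explanations.

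DCP_22 control probes were brighter on the slide with poly I:C. A hybridisation or wash that let all mismatched control probes bind more would raise the DCP_20 series as well. Its 4 probes that were unsaturated and well above background on all 16 arrays rose by a median of 1.23 (1.17 to 1.3), all less than 50% of the median for DCP_22. Spike-in probes also lay higher against the 75th percentile on that slide (1.295 to 1.49, compared with -0.153 to 0.072). Within DCP_22 the rise was uneven and grew with probe number, from 2.21 for DCP_22_0 to 6.43 for DCP_22_9. The comparison of the 2 medians therefore left this explanation open. The DCP_1 probes, saturated or at background, could not show such a rise. A transcript raised by poly I:C that binds these probes could not be tested, since 0 arrays with poly I:C lay on the other slide, so it cannot be told apart from a difference between the slides.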

How the results depend on the processing

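Settings of the probe sets, outlier spots kept, the side of the slide and array position as blocks, spike-in scaling, saturated probes left out and the 8 arrays of a slide were chosen after the data were seen. Of the tests of named probes under other settings, 812 kept direction and call, 61 lost the call and none reversed. The 812 include 40 with the 2-fold threshold and 28 with the slide as a block, neither of which could change a named call. The losses were mostly in probes near background, which limits what these arrays can measure. The slide as a block gave no value for poly I:C contrasts and changes no other by construction. Gene lists and the IRF10 probe gave no value under any setting. Causes were not tested, except that a 2-fold threshold cannot give more calls by construction.

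With only the groups of the contrast, calls were 27 for IRF10 without poly I:C, 12 with it, 288 and 188 for the vector without and with poly I:C and 235 for their interaction. The arrays of a slide gave 31, 48 and, for the vector with poly I:C, 301. The 2-fold threshold gave 31, 8, 15 for the mean IRF10 effect, 18 for its interaction, 213, 252 and 231 for poly I:C without plasmid, with vector and with IRF10, and 36, 100 and 75 for the vector. Median scaling gave 179 for IRF10 with poly I:C, 265 for the mean and 20 for the interaction. Normexp correction gave 16 for the interaction and 1730 for poly I:C in vector cells. No filter gave 25, 61 and 13 for IRF10 with poly I:C, mean and interaction, 4282 for poly I:C in vector cells, and 246, 299 and 187 for the vector. Spike-in scaling gave 36, 75 and 16 for the same IRF10 contrasts, 4881, 4969 and 4984 for poly I:C, and 229, 352 and 255 for the vector. Array position as a block gave 6 interaction calls and probes without saturation 20.

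With the replicate number as a block, calls were 86, 117, 138 and 27 for the 4 IRF10 contrasts, 2259, 2650 and 2758 for poly I:C, and 513, 549 and 411 for the vector. In the comparison of vector cells, where same-numbered arrays deviated together, by number or by position, the block changed no named call. In the other comparisons r was from -0.13 to 0.103 and the numbers did not pair the arrays, though same-numbered arrays of a treatment on both slides also shared a position.

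The correlation of the IRF10 effects was 0.456 with normexp correction, 0.153 with no filter, 0.208 with probes above background on all arrays, 0.559 with the side of the slide as a block and 0.42 without saturated probes. That of vector and poly I:C effects was 0.686, 0.485, 0.671, 0.616 and 0.622 in the same order, against 0.644 over all probes. The side of the slide was a single term fitted over both slides, with all IRF10 arrays on the same side. Its error entered both IRF10 effects alike, so their 0.559 can be higher for that reason alone.

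Probe sets are given as the difference of their median from that of other probes. Their members were first taken again under each setting; after reversals were seen, members were fixed, and both ways are given. In IRF10 with poly I:C, probes raised by the vector had -0.319 with an estimated correlation (adjusted p = 0.347), and -0.0114 with probes above background on all arrays, either way. fry, which tests the set against no change and not against other probes, gave an adjusted p of 0.148 for its median of -0.3307. Taken again the probes had -0.251 with median scaling and 0.00972, reversed, with normexp correction. Probes raised by poly I:C had -0.106 with an estimated correlation (adjusted p = 0.182) and with median scaling (0.0738), and -0.098 taken again with no filter. In IRF10 without poly I:C, taken again with no filter, they reversed to 0.0784. Probes lowered by poly I:C, taken again with spike-in scaling, had -0.0176 without poly I:C (adjusted p = 0.622). With poly I:C, where the set was not called, they had 0.0135 with median scaling (adjusted p = 0.0386) and reversed to -0.0163 with quantile normalization, -0.00193 with normexp correction, -0.0178 taken again with spike-in scaling and -0.0213 with the side of the slide as a block.

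Leaving out each array gave calls of 43 to 55 for IRF10 without poly I:C, 35 to 67 with it, 85 to 119 for the mean, 13 to 30 for the interaction, 1742 to 1946, 2297 to 2464 and 2467 to 2576 for poly I:C, and 205 to 380, 292 to 531 and 194 to 380 for the vector, where a lone vehicle array was assumed to vary like the other groups. The correlations were 0.352 to 0.403 and 0.61 to 0.668. Sets of vector-raised probes had 0.337 to 0.38 and 0.704 to 1.04 for the vector, and -0.451 to -0.359 and -0.383 to -0.219 for IRF10. Those raised by poly I:C had -0.248 to -0.179 and -0.182 to -0.0698, and those lowered -0.149 to -0.0812 and -0.0283 to 0.0287.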

Other observations

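The test in this part was chosen after the data were seen. Reverse-strand and forward-strand contig probes were raised by poly I:C about equally often. Without plasmid, 69 of the 4710 reverse-strand probes on the array rose at least 2-fold (1.46%), compared with 67 of 4727 forward-strand probes (1.42%), an odds ratio of 1.03 (two-sided Fisher's exact p = 0.86). Among tested probes the shares were 3.63% and 2.21% (Fisher's exact p = 0.0041), but 40.3% of reverse-strand and 64.1% of forward-strand probes were bright enough to test, and a probe could pass that filter through the raised group alone. Probes of neighbouring contigs may come from 1 gene and are not independent, and the comparison lies across slides, where spike-in scaling gave 48 rises in place of 1179.

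Of 1421 contigs with both strands tested, 12 were raised at least 2-fold on both, 18 on the forward strand only and 27 on the reverse strand only. The poly I:C effects of the paired probes had r = 0.452 across contigs. The strand of the transcript was not given for any contig, so no contig was assigned a sense and an antisense probe.

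POC02895_1 was also higher with poly I:C in cells without the IRF10 plasmid. It was at -5.33 ± 0.02 in controls and -3.64 ± 0.08 with poly I:C (SD, n = 2 each), and at -5.21 ± 0.47 and -2.19 ± 0.08 in vector cells (n = 3 each). It was well above background only with poly I:C in these groups. Both comparisons lie across the slides. The spike-in mean, scaled alike, went from -0.096 and -0.056 on control arrays to 1.49 and 1.45 with poly I:C. On vector arrays it went from -0.082 to -0.018 up to 1.295 to 1.39. A response of this contig to poly I:C was therefore not separated from slide and scaling.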
